A study of Mus musculus with 6 samples.

How the data were processed

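MicroRNAs (miRNAs) were measured by SYBR Green quantitative PCR in RNA from serum exosomes, small vesicles that cells release into the blood. The serum came from mice 2 weeks after ACLT, taken here as transection of the anterior cruciate ligament, the surgical model of joint instability and osteoarthritis. Per the labels, 3 samples came from mice given vehicle and 3 from mice given OCExoInhib. The labels do not spell out this name, and the known study behind it describes an inhibitor of exosome release directed to osteoclasts, the bone-resorbing cells. The design text says that equal amounts of exosomal miRNA from 3 mice per group were pooled, and it does not say whether the 3 samples of a group are separate mice or separate runs of a pool. P-values therefore measure only the spread between these samples, which may be technical.

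Per the labels' protocols, RNA was purified with a column kit for exosomal RNA, reverse transcribed and profiled with a mouse exosome miRNA kit on a ViiA7 instrument for 40 cycles. The deposited raw values are threshold cycles (Ct), per the file headers, where a lower Ct is a higher level and 1 cycle is about 1 doubling. The fluorescence threshold and the rule for wells without a Ct are not given in the sources used here. The deposited normalized values are on a log2 scale, as differences of Ct from a spike-in control per the file headers. The header gives 2 to the power of the negative difference as an example, but the values are the differences themselves. In every sample they equal the raw Ct minus the mean Ct of wells P21, P22 and P23, whose RNA the file does not name. The authors' deposited fold table holds the ratio of vehicle over OCExoInhib, and it was used only for comparison. The tables held 0 columns of per-sample values beyond the 6 samples.

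The plate had 384 wells, 380 of them with a named miRNA. A Ct was given in all 6 samples for 126 wells, which are 123 named miRNAs and the wells P21 to P23. The same 258 wells had no Ct in any sample, and 0 wells had a Ct in only some samples. The depth of such an array is set by its cycles, and a value at Ct 35 or later rests on few template molecules. Tests covered the 115 miRNAs with a Ct under 35 in at least 3 of the 6 samples, and 8 named miRNAs with later cycles were left out. The log2 level of a miRNA is the negative of its deposited normalized value, and log2 differences are OCExoInhib minus vehicle.

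Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 115 miRNAs and a threshold of 0.05. Single measures were compared with exact two-sided permutation tests in scipy 1.17.1 under Python 3.11.15, whose smallest possible p for 3 samples against 3 is 0.1. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The groups, tests, lists, rule for named miRNAs and the alternatives not said below to be added were fixed before the data were examined.

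There were 23 lists. They covered osteoclast differentiation (promoting and restraining), cartilage and osteoarthritis, reported regulators of Timp3, and endothelial, erythrocyte, platelet, leukocyte, liver, muscle and brain miRNAs. Others were the let-7, miR-15 and miR-16, miR-29, miR-30, miR-34 and miR-449, and miR-200 families, and the miR-17-92, miR-290, Dlk1-Dio3, Sfmbt2 and X-linked testis clusters. The last list held reference RNAs such as U6, and 0 of its entries were on the panel under these names. A list was tested when at least 3 members were, which left 18. Members were matched by miRNA name.

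Named miRNAs are the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, up to 4 members of each list with the smallest p, the reference wells, miR-451 and miR-23a, and up to 10 of the largest folds each way in the authors' table. List members that did not pass are mostly given as counts. Any miRNA named outside this rule is said to have been chosen after its values were seen.

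The tests were checked on 50 simulated sets of 115 miRNAs with the spread of this comparison. A log2 change of 1 was called in 3% of cases, a change of 2 in 27.3%, a change of 3 in 57% and a change of 5 in 89%, and 0.418% of miRNAs without a change were called. The list test gave an unadjusted p under 0.05 for 4% of 900 lists with no shift. The simulated noise was independent between miRNAs and samples, without the Ct differences shared between miRNAs that are described below. These rates need not hold for the measured values.

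Alternatives were other normalizations (global mean, quantile, none), other Ct limits, late cycles set to missing, the sample number as a block, each sample left out, other variance models and an unmoderated test. Added after seeing the data were the exclusion of miRNAs with a repeated Ct difference, vehicle samples 1 and 3 averaged, Ct above 35 set to 35, and centring by sample medians or by median-of-ratios. A planned haemolysis index, the Ct of miR-23a minus that of miR-451, was not computed because both wells had no Ct. A planned pseudocount alternative did not apply, since the normalized values are not linear. Planned reference-RNA normalization used wells P21 to P23 and equals the deposited normalization. Positions in the genome are not given, since the sources used here name no build.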

Results

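Serum exosomal miRNAs were profiled in 3 vehicle and 3 OCExoInhib samples taken 2 weeks after ACLT. The comparison asks which circulating exosomal miRNAs differ when mice with an injured joint receive OCExoInhib. Of the named miRNAs, 123 had a Ct in every sample. Panel members with no Ct in any sample included miR-451 and miR-486 of red cells, miR-122 of liver, miR-126-3p of endothelium, and miR-142-3p and miR-155 of leukocytes. These examples, apart from miR-451, were chosen after their values were seen. The number of named miRNAs with a Ct under 35 was 109 ± 0.577 in vehicle and 114 ± 2.52 in OCExoInhib samples (SD, n = 3 each). The difference of 5.67 had an exact two-sided permutation p of 0.1, the smallest this design can give. It was 5.67 below Ct 32 (exact p 0.2) and 1 below Ct 38 (exact p 1). The 7 miRNAs called higher below held 17 vehicle values and 0 OCExoInhib values at Ct 35 or later. The difference under Ct 35 thus largely counts these same miRNAs. The median SD within a group was 0.878 cycles.

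Relative to the normalizer wells, the 3 OCExoInhib samples of serum exosomes held less of 20 miRNAs and more of 7 than the 3 vehicle samples. With global mean, quantile and no normalization the counts were 14, 9 and 15 lower, each with 7 higher. Centring each sample on its median, chosen after seeing the data, turned the balance to 11 lower and 57 higher. That centring moved the median log2 difference of all tested miRNAs from −0.54 to 1.98. Median-of-ratios centring, also chosen after seeing the data, gave 17 lower and 7 higher. On the deposited normalization, 19 of the 20 falls and 3 of the 7 rises carried a Ct difference that repeated between samples, described below. Without the miRNAs that carried one, an exclusion also chosen after seeing the data, 1 fall and 4 rises passed. Falls of over 100-fold on the deposited normalization were those of miR-107, 303.6-fold lower (log2 difference −8.25, SE 1.38, limma adjusted p 0.000193), miR-30d, 162.7-fold lower (−7.35, SE 0.97), miR-148a, 141.2-fold lower (−7.14, SE 0.89), and miR-542-3p, 129.6-fold lower (−7.02, SE 0.78). miR-652, miR-16, miR-194, let-7e, miR-378, miR-21, miR-15a and miR-30a fell by between 46.6-fold for miR-652 and 15.7-fold for miR-30a. The rises were those of miR-501-3p (log2 difference 6.65, SE 0.89), miR-34a (6.07, SE 1.01), miR-28 (5.80, SE 0.95), miR-140 (5.80, SE 0.82), miR-29c (5.68, SE 0.75), miR-127 (5.61, SE 0.82) and miR-425 (4.79, SE 0.88).

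The sizes and order of the folds rested on single samples. miR-107 had a Ct of 36.996 in OCExoInhib 2, and its log2 difference was −6.22 without that sample and −10.13 without OCExoInhib 3. With Ct above 35 set to 35 it was −7.58, which limits the effect of this late value only and is not a lower bound on the fall. Its adjusted p was 0.112 by the unmoderated equal-variance test, the highest over the settings tried, against a lowest of 1.0e-12 without vehicle 2. The log2 difference of miR-30d was −8.51 without vehicle 2 and −6.74 without vehicle 3, and that of miR-148a −7.89 without vehicle 1 and −6.20 without vehicle 2. Without OCExoInhib 2 the order was miR-148a (−7.26), miR-542-3p (−7.23), miR-30d (−6.93) and miR-107. Leaving out a sample moved the fold of 18 of the 27 miRNAs by over 1.5 times.

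For all 27 miRNAs the 3 samples of one group lay wholly above the 3 of the other. Among the 88 that did not pass, 3 showed this pattern. Chance gives it to 10% of unselected miRNAs. Both sets were selected by a test on these same values, so the counts are no separate support for the calls. The levels from which the miRNAs fell or rose differed. Those that fell had mean vehicle Ct values from 23.8 to 28.5 and mean OCExoInhib values from 30.2 to 32.5. Those that rose had mean vehicle Ct values from 35.3 to 36.9, with 17 of the 21 single values at 35 or later, and mean OCExoInhib values from 29.3 to 29.9. With late values set to Ct 35, a setting chosen after seeing the data, the rises were at least 16.5-fold for miR-425 to at least 30.0-fold for miR-140. In OCExoInhib samples all 27 thus had mean Ct values between 29.3 and 32.5, a range that also held 26 of the 88 other miRNAs (29.5%). The upper end was that of miR-107, and the next highest mean was 31.0 for miR-194. Apart from miR-107 at −2.31, mean OCExoInhib levels relative to wells P21 to P23 ran from −0.86 for miR-194 to 0.87 for miR-140. In vehicle samples they ran from −6.02 for miR-501-3p to 7.15 for miR-30d. Whether they fell or rose, these miRNAs thus lay near the wells' mean OCExoInhib Ct of 30.2. The cause was not tested.

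**Figure D1:**
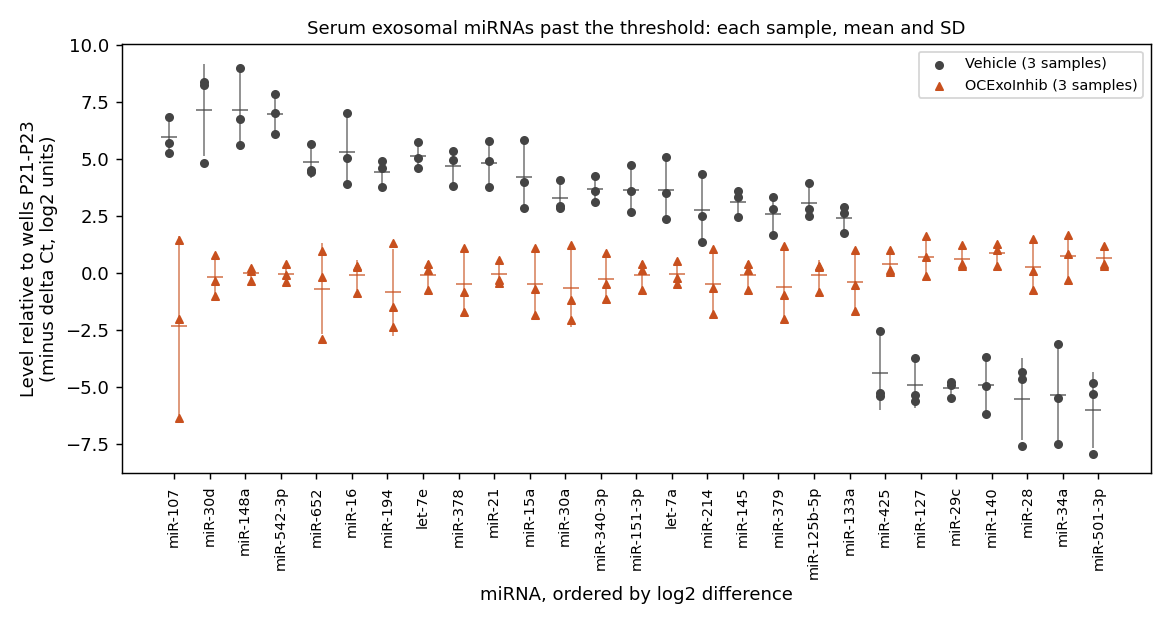
Level of each of the 27 miRNAs past the threshold, as negative Ct difference from wells P21 to P23 in log2 units, for each vehicle (circles) and OCExoInhib (triangles) sample, with the mean (dash) and SD (bar) of 3 samples. The groups do not overlap for any of the 27, and the spread of miR-107 among OCExoInhib samples (SD 3.92) is the widest.

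Many of the miRNAs that passed shared a constant Ct difference between samples of a group. Vehicle 1 minus vehicle 3 was 0.939 cycles, within 0.0015, for 17 miRNAs, all of which fell. OCExoInhib 1 minus OCExoInhib 2 was 0.570 for 10 miRNAs, and OCExoInhib 1 minus OCExoInhib 3 was 1.886 for 10. The difference between OCExoInhib 2 and OCExoInhib 3 was 1.316 for 5, of which 4 passed the threshold. For let-7e, miR-145 and miR-151-3p, the last named after its values were seen, the Ct values of OCExoInhib 1, 2 and 3 were the same 31.087, 30.517 and 29.201. Of the 27 miRNAs, 22 had at least 1 of these differences, 19 of the 20 that fell and 3 of the 7 that rose. Without the miRNAs that carried one, an exclusion chosen after seeing the data, 5 of 92 passed, with a fall of miR-542-3p and rises of miR-140, miR-127, miR-28 and miR-425.

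**Figure D2:**
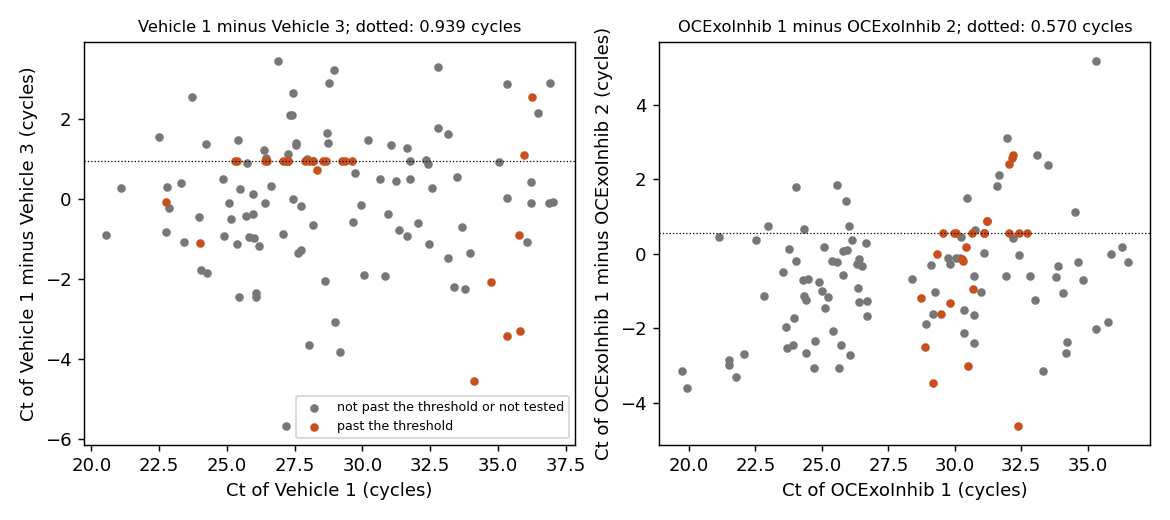
Ct difference between vehicle 1 and vehicle 3 (left) and between OCExoInhib 1 and OCExoInhib 2 (right), in cycles, against the Ct of the first sample, one point per miRNA. Points of miRNAs past the threshold (orange) line up on the dotted lines at 0.939 cycles for 17 miRNAs and 0.570 cycles for 10, while the others (grey) scatter.

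Among miRNAs that promote osteoclast differentiation, 4 of the 7 tested fell. These were miR-148a, miR-21 (log2 difference −4.87, SE 0.80), miR-214 (−3.20, SE 0.94) and miR-133a (−2.82, SE 0.84). miR-214 is also known to be released by osteoclasts in exosomes and to restrain osteoblasts, and miR-133a is best known from muscle. miR-29c rose and 2 others did not pass. The median log2 difference of the list was −2.82, and camera gave p 0.187 (adjusted 0.48, and 0.679 with an estimated correlation). With a Ct under 35 required in all samples, or late values set to missing, the list test was the same and kept 6 members. Both settings dropped miR-29c, the only member that rose, because its vehicle values were late. Camera then gave p 0.0033 downward (adjusted 0.0528), not past the threshold. Since the rise itself decided the removal, this lower p is no separate support for a fall of the list. Over the other camera settings the adjusted p ranged from 0.409 to 0.679. Fry gave an adjusted p of 0.0283, the same as for the platelet, muscle, Timp3, miR-30, and miR-15 and miR-16 lists. Among 5 tested miRNAs that restrain osteoclast differentiation, miR-34a rose and 4 did not pass (camera adjusted p 0.48). The calls of miR-214 and miR-133a depended on single samples. The adjusted p of miR-214 was 0.102 without vehicle 2, 0.122 without OCExoInhib 1 and 0.0583 without OCExoInhib 3. That of miR-133a was 0.0762 without vehicle 3, 0.121 without OCExoInhib 1 and 0.0608 without OCExoInhib 3. Over all settings tried, including centring by sample medians, the adjusted p ranged from 0.00266 to 0.465 for miR-214 and from 0.00451 to 0.733 for miR-133a. All members of the promoting list that changed carried a repeated Ct difference, as did miR-34a.

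Of 6 tested cartilage and osteoarthritis miRNAs, miR-140 and miR-34a rose and miR-145 fell (log2 difference −3.20, SE 0.76, adjusted p 0.00379). miR-140 is enriched in cartilage and restrains the aggrecan-cleaving protease Adamts5, and miR-145 represses the chondrocyte factor Sox9. miR-140 was measured at a mean Ct of 29.3 ± 0.0400 in OCExoInhib and 35.9 ± 0.938 in vehicle samples (SD, n = 3 each), with 2 vehicle values at 35 or later. The median of the list was −0.61 and its mean 1.08, opposite in sign, and camera gave p 0.0927 upward (adjusted 0.48). With a Ct under 35 required in all samples, or late values set to missing, 3 members were tested and the direction turned downward (p 0.54, adjusted 0.617). Both members that rose, miR-140 and miR-34a, were among those dropped, because of their late vehicle values. The turn follows from this removal and is no evidence of a fall. Among 6 tested miRNAs reported to target Timp3, which encodes an inhibitor of matrix proteases, miR-21 fell and 5 did not pass (camera adjusted p 0.646). Among 5 endothelial and angiogenic miRNAs, miR-378 fell by 36.2-fold and 4 did not pass (camera adjusted p 0.65). miR-34a, miR-145, miR-21 and miR-378 carried repeated Ct differences and miR-140 did not.

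Markers of other cells that contribute to serum RNA were measured in part. Of 4 tested erythrocyte miRNAs, miR-16 fell by 42.4-fold (log2 difference −5.41, SE 0.88) and 3 did not pass. Of 3 platelet miRNAs, miR-21 fell. Of 3 muscle miRNAs, miR-133a fell. The 2 tested liver miRNAs included miR-194, which fell by 38.7-fold. Neither of the 2 tested leukocyte miRNAs passed, nor did the 1 tested brain miRNA. Camera's adjusted p was 0.646 for the erythrocyte and platelet lists and 0.652 for the muscle list, and the lists with fewer than 3 tested members had no list test. miR-16, miR-21, miR-133a and miR-194 all carried repeated Ct differences.

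In families of related sequence some members passed the threshold and others did not. Whether the assays tell such sequences apart was not tested. In the let-7 family let-7a (log2 difference −3.70, SE 0.84) and let-7e (−5.18, SE 0.76) fell and 4 others did not pass. Neither let-7a (adjusted p 0.251) nor miR-30a (0.287) passed with quantile normalization, and each was lost in 5 of the settings tried. In the miR-30 family miR-30a (−3.98, SE 0.90) and miR-30d fell and 3 did not pass, among them miR-30b (−0.89, SE 0.81, but above 0 with global mean normalization). In the miR-15 and miR-16 family miR-15a (−4.70, SE 0.95) and miR-16 fell and 2 did not pass. In the miR-29 family miR-29c rose and 2 did not pass, including miR-29a (−0.97, SE 0.89, but above 0 with global mean normalization). Of 5 tested miR-34 and miR-449 members only miR-34a passed. None of the 5 tested members of the miR-17-92 cluster and its paralogs passed, nor any of 4 in the miR-200 family. Among imprinted Dlk1-Dio3 miRNAs, 44 of 50 on the panel had no Ct, miR-127 rose, miR-379 fell (−3.19, SE 0.90, adjusted p 0.0133) and 4 did not pass. The adjusted p of miR-379 was 0.0750 without OCExoInhib 2 and 0.0546 without OCExoInhib 3, and ranged from 0.00244 to 0.465 over all settings. Among these, miR-127 carried no repeated Ct difference, and the other family and cluster members that passed did. None of the 5 Sfmbt2, 3 X-linked testis or 2 miR-290 cluster miRNAs passed by limma.

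Camera placed 0 of the 18 lists past the adjusted threshold, with 0 at an unadjusted p under 0.05. Its smallest p was 0.0924, for the miR-30 family, and the smallest adjusted p was 0.48, or 0.679 with an estimated correlation. Fry, which tests whether a list moves one way on balance and not whether it differs from other miRNAs, placed 8 lists past the threshold. All 8 moved downward, as did the median of all tested miRNAs on this normalization. They were the osteoclast-promoting, Timp3, erythrocyte, platelet, muscle, let-7, miR-30, and miR-15 and miR-16 lists. For every tested list the counts of rises and falls adjusted over the list alone equalled those over all 115 miRNAs.

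The authors' deposited table gave the same folds. Its log2 values differed from those of the group means of the normalized values by a median of 0.000229 and at most 0.0345, with the same sign for 100% of 123 miRNAs. The deposited folds of vehicle over OCExoInhib left a gap. Those of the miRNAs that did not pass ranged from 0.661 to 1.997, none lay from 2 to under 7, and the smallest fold of the miRNAs that fell was 7.07, for miR-133a. The largest unadjusted p of a miRNA that passed was 0.00431, and the smallest of the others was 0.24, where 21.1 of 88 miRNAs without a change would lie below that value.

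**Figure D3:**
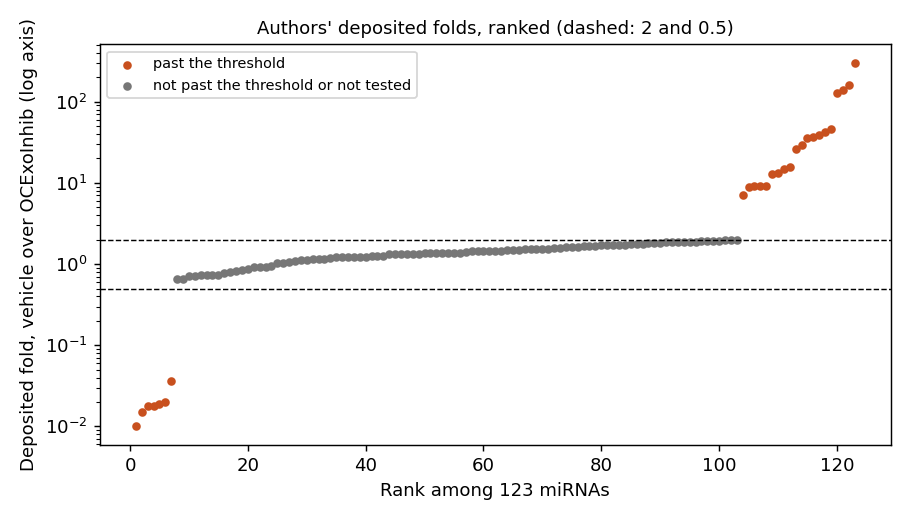
Deposited fold of vehicle over OCExoInhib (log axis) for 123 miRNAs in order of size, with dashed lines at 2 and 0.5. Grey points lie between 0.661 and 1.997, and the orange points past the threshold stand apart from them on both sides.

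The wells that set the normalization had a mean Ct of 30.9 ± 0.318 in vehicle and 30.2 ± 0.531 in OCExoInhib samples (SD, n = 3 each). The difference of −0.725 cycles had an exact two-sided permutation p of 0.2. The single wells differed by −1.004 (P21, exact p 0.1), −1.20 (P22, exact p 0.2) and 0.035 cycles (P23, exact p 0.9). Against the mean Ct of the 101 miRNAs under 35 in all samples the wells differed by −1.18 cycles (exact p 0.1). These 101 held 19 of the miRNAs that fell and 0 of those that rose. The calls themselves therefore contribute to this difference, and to the global mean normalization, which rests on the same 101. The median log2 difference over all 115 miRNAs was −0.54, against 0.64 with global mean, 0.20 with quantile and 0.18 with no normalization. With quantile normalization 16 miRNAs passed. None of the 27 changed sign under any normalization tried.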

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

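The averaging of vehicle samples 1 and 3, the capping of Ct at 35, the 2 centring methods and the exclusion of miRNAs with repeated Ct differences were chosen after seeing the data. Leaving out each sample in turn gave 24 to 27 changed miRNAs, 17 to 20 lower and 7 to 7 higher. It gave 0 to 0 lists by camera, differences of 4.33 to 6.83 in miRNAs under Ct 35, and differences of −0.942 to −0.429 cycles in the reference wells. Same-numbered samples correlated by 0.0587, 0.0177 and 0.117 in their deviations from the group means, so the numbers were not taken as pairs. With the sample number as a block there were 25 changed miRNAs (18 lower, 7 higher) and 0 lists. Sample 2 of OCExoInhib correlated better with another number than its own. Global mean normalization kept 21 of the 27 calls, no normalization 22, median-of-ratios centring 24 and the trended robust variance 27.

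Other settings moved counts by more than 1.5 times. Quantile normalization gave 16 changed miRNAs, 9 of them lower. Without miRNAs that carry a repeated difference there were 5, 1 lower and 4 higher, because 22 of the 27 were left out. Centring on sample medians gave 68, 11 lower and 57 higher, with 18 shared calls, and it moved the median of all miRNAs to 1.98. The unmoderated equal-variance test gave 15 after adjustment, 11 lower and 4 higher, and 26 unadjusted. A Ct under 35 in all samples left 0 higher, since their vehicle values are late, and late values set to missing left 3 higher. Fry called 8 lists. The authors' folds differed from global mean folds by a median of 1.18 on the log2 scale. That is the wells' difference of −1.18 cycles against the miRNAs of the global mean, which moves every miRNA alike. Apart from this, the filter and the exclusion, the cause was not tested.

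No called miRNA reversed, and miR-214 was lost most often, in 10 settings. Among miRNAs that did not pass, miR-103 turned to 0.54 with global mean, 0.90 with quantile, 0.083 with no normalization and 1.88 with median centring, and it ranged from −1.58 to 0.12 (without vehicle 3) with samples left out. With global mean and median centring, miR-29a turned to 0.21 and 1.55 and miR-30b to 0.29 and 1.64. The alternatives for the haemolysis index and the pseudocount were not run. The sizes of the 7 rises rest on late vehicle cycles, although their SEs, from 0.75 to 1.01, lay around the median SE of 0.827.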

Other observations

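The tests of neighbouring genes, repeated differences, folds and normalizer wells and the count over splits were chosen only after the result was seen, while the limma calls and the normalizations named here were planned. The 5 miRNAs with the lowest Ct, also named after their values were seen, were miR-489, miR-29a, miR-19a, miR-33 and let-7d. Ct values of different assays do not order the levels of their miRNAs, since assay efficiencies are not given. miR-489 had a mean Ct of 20.7 ± 0.510 in vehicle and 20.4 ± 0.959 in OCExoInhib samples, and miR-29a 20.98 ± 0.460 and 21.2 ± 2.00 (SD, n = 3 each). None of the 5 passed the threshold by limma.

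Of 33 pairs of tested miRNAs with at most 3 base differences, 17 had no call, 14 had 1 and 2 had both, which were let-7a with let-7e and miR-30a with miR-30d. Calls placed at random would give 1 call in about 12 pairs. miR-107 (AGCAGCAUUGUACAGGGCUAUCA) had 1 OCExoInhib value past Ct 35. It fell by 7.58 on the log2 scale with this value set to Ct 35, and its log2 difference was −6.22 without that sample. miR-103 (AGCAGCAUUGUACAGGGCUAUGA), 1 base away, had a difference of −0.64 (SE 0.90), which was above 0 with global mean, quantile or no normalization. miR-29c (UAGCACCAUUUGAAAUCGGUUA) had all 3 vehicle values at Ct 35 or later and rose by at least 4.70, and miR-29a (UAGCACCAUCUGAAAUCGGUUA), 1 base away, had −0.97, or 0.21 with global mean normalization. The differences between these pairs were not tested, nor was whether the assays tell their sequences apart. Neighbouring miRNA genes, which can share a transcript, were compared through the gene table for 105 tested miRNAs. Of 42 pairs within 10 kb, 17 had 1 call and 1, miR-15a with miR-16, had both. A hypothesis that neighbours change together was tested by permuting the differences, and the mean distance between neighbours gave p 0.365, which leaves it open.

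The samples allow 10 splits into 3 and 3, and 1 of them, the real one, gave as many as 27 changed miRNAs, with 0 for the highest of the others. These splits are too few for a share under 0.05.

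The first pattern is the repeated Ct differences. In 10000 simulated sets of differences with the measured spread of vehicle 1 minus vehicle 3, at most 5 wells shared one value, against 17 observed. This argues against coincidence for that pair, the only one covered. The difference between OCExoInhib 2 and OCExoInhib 3 was shared by 5 wells, no more than this maximum, which holds only for the vehicle pair. For let-7e, miR-145 and miR-151-3p it follows from the OCExoInhib differences of 0.570 and 1.886, which these miRNAs also carried. An effect of the instrument or plate on all wells of this range is argued against by 40 other miRNAs with vehicle 1 Ct values from 25.291 to 29.62, of which 0 had the difference, a share of up to 8.81% (95% bound). The repeated differences are of raw Ct, so subtracting the normalizer wells cannot have made them. For this vehicle pair the repeated 0.939 cycles also differ from the wells' own difference of −0.199. Whether the samples were measured separately in the wells with a repeated difference stays open. The sources used here do not record how single Ct values were obtained. Calls that carry a repeated difference may therefore rest on fewer than 3 separate measurements per group.

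The second pattern is the gap in folds. Of the 88 miRNAs that did not pass, 0 differed by 2-fold to under 7-fold. In 10000 random rotations of their within-group deviations, which keep the spread of each miRNA and the correlation between them, the number was at least 6, with a median of 20, which argues against a chance gap in a continuous range of folds. A candidate explanation is a 2-fold limit in the choice of deposited miRNAs. The miRNAs that did not pass ended at 1.997 on one side, where 16 deposited folds lay from 1.8 to under 2. From 2 to under 2.2 there were 0, as such a limit would give. On the other side these miRNAs ended at 0.661, with 0 folds from 0.5 to under 0.6, which leaves this open. A biological source of 2 separate classes of miRNA, set by OCExoInhib, would still leave the unchanged class with the measured spread. In the rotations that spread alone placed at least 6 of the 88 in the range, against 0 observed. This argues against 2 biological classes as the source of the gap. Whether such classes exist was not tested.

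The third pattern is the balance of miRNAs that did not pass, of which 71 of 88 lay below 0, with a median of −0.444. On unnormalized cycles the median was 0.281 and 22 lay below 0. This change is fixed by the wells' difference of −0.725 cycles, which is added to every miRNA alike, so it tests neither explanation. An earlier Ct of the normalizer wells in OCExoInhib samples and a lower miRNA yield from their serum both stay open. The difference of the wells had an exact permutation p of 0.2, and equal RNA amounts were used per the design text, so a lower yield need not show.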
